A study of Mus musculus with 53 samples.

How the data were processed

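Lung tissue of 53 mice was measured on 53 arrays, 1 per mouse, in 9 groups. Per the labels' protocols, the small lobe was preserved and stored frozen, samples were randomized before RNA extraction, and 50 ng of total RNA per sample was amplified to cDNA with the NuGEN Ovation system and labelled with biotin. The deposited signal intensity values were made by the authors with MAS5, per the submitters' processing notes, and are on a linear scale. They had been scaled by the authors so that the 2% trimmed mean of every array is 150, which was checked on all arrays. The deposited detection p-value of each probe set is also a MAS5 output, and present calls in the files had a detection p of at most 0.0488. The series table and the tables per sample held identical signals (largest difference 0), so the choice between them changed nothing. The version of MAS5 was not given in the sources used here. The 5′ and 3′ control probe sets of Gapdh and actin gave the 3′/5′ ratios, which are measures of RNA integrity and ran from 1.40 to 2.42 for Gapdh and from 1.67 to 2.88 for actin.

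A value of 16 was added to each signal before the log2 was taken. Probe sets were kept when called present at a detection p under 0.05 on at least 50% of the arrays of at least 1 group, which left 35615 of 45101. Of all probe sets 34945 had 1 gene symbol, 932 several and 9160 none, and 64 were controls. Entrez IDs matched 34741 probe sets to the reference gene table of the assembly GRCm38.p6, and no symbol needed an update. The array itself has no genome build, so no positions are given. Each gene was represented by its brightest kept probe set, which gave 15031 genes, and 7328 of them had more than 1. Folds are those of the log2 values with 16 added, and lie under the ratio of the signals where signals are low. A fold against a group in which the gene was not called present is given as at least that fold.

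Groups were compared in R 4.3.3 with limma 3.58.1 on all 53 arrays, with 1 mean per group, the comparison as a contrast and a variance trend (eBayes with trend). The tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. All adjusted p-values of single genes are from this fit. There were 11 comparisons of groups and 4 tests of a difference between effects. Gene lists for lung cell types and smoke-related pathways, 37 lists with 667 entries of which 595 were tested, were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists within a comparison. Of 555 list tests 231 were called, and 70 were called when the correlation was estimated from the data. In the report that second value is printed where it ended a call. The share of the 12-week effect seen in a later group is the slope through 0 of the later effects on those at 12 weeks, with a jackknife SE over arrays. Comparisons with a shared control were set beside 100 simulations of unchanged groups and beside a split of the controls. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

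Groups, comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, apart from those named here as later. The rule took the 8 largest rises and 8 largest falls among called genes in the smoke and cessation comparisons, and the 5 and 5 largest in the comparisons with untreated mice and the tests of differences. It added up to 4 called members with the largest change from each called list, and a panel of 18 genes given whatever their result. Transcripts without a gene name were passed over. The rule did not cover the largest changes between the 2 cessation groups, and the 5 and 5 largest there were added after the values were seen. The rule gave 986 gene results, of which 808 passed the test. For 393 of them the gene had more than 1 kept probe set, and for 3 another probe set was called in the opposite direction.

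Alternatives chosen beforehand were quantile normalization, a pseudocount of 1, no detection filter (18194 genes), only the compared groups in the fit, all kept probe sets, the last number in the sample title as a covariate, a minimum absolute log2 change of 1, leaving out each array in turn, and for the lists an estimated correlation and the probe set with the largest spread per gene, and for the share the genes called at 2 weeks. Others were added after the data had been seen. The last numbers in the sample titles, whose meaning is not stated, were cut into 3 ranges (2 to 54, 57 to 134 and 137 to 158, with 16, 27 and 10 arrays). The cuts were placed where they best parted the arrays on the leading component of the residuals, and were placed anew for each shuffle. The leading component of the residuals held 20.4% of the residual variance, and 76.3% of that component lay between the ranges (permutation p = 0.001, the smallest possible with 999 shuffles). The ranges were therefore used as a block. The other additions left out 3 arrays whose highest signal was far above that of the rest, left out 7 arrays with a high 3′/5′ ratio, used both ratios as covariates, or used the number within the group in the title as a block. The lists were also tested with the block, and the share of the smoke effect also over genes that changed by under 1 on the log2 scale. The median change of all genes lay from -0.03 to 0.03 on the log2 scale over the comparisons of the primary fit.

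The fit was tested on simulated data with known changes in 200 of 15031 genes. For smoke at 2 weeks it called 94% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2, with 10 unchanged genes called. For smoke at 12 weeks it called 89.6%, 98.5% and 100%, with 9 unchanged genes called, and for the cessation groups against each other 89.6%, 100% and 100%, with 9. In the 12-week simulation camera called 10 of 10 shifted lists and 1 of 20 unshifted lists with either correlation. The simulated noise was independent between genes, so this run cannot tell how either setting fares where genes vary together. A true share of 30% was recovered as 29.7%. Probe sets with several or no gene symbols were left out of the gene tests and counted apart.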

Results

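Gene expression was measured in the small lobe of the lung of female C57BL/6 mice that had breathed cigarette smoke, sham air or nothing but cage air. Each of 53 mice gave 1 Affymetrix Mouse 430 2.0 array. Exposed mice were held in nose-only chambers and breathed 4% mainstream cigarette smoke or forced air for 2 hours a day on 5 days a week. Forced air is the sham procedure, with the same handling and no smoke. Smoke and forced air groups were taken after 2, 12 and 24 weeks, with 6 mice per group except for 5 mice after 12 weeks of smoke. A pair of cessation groups of 6 mice each had 12 weeks of smoke and then 12 weeks of either forced air or room air, and are called here smoke-to-forced-air and smoke-to-room-air mice. The treatment protocol gives sham exposure after smoke for all cessation mice, while the group labels separate forced air from room air. The group labels were followed, so the meaning of room air rests on them. A further 6 mice were untreated and are labelled with a time of 0. Where they serve as a zero line, time, age and procedure differ together between them and the other groups. Forced air of the same week therefore remains the control of smoke. No group breathed room air alone for 24 weeks, so forced air at 24 weeks was the control of both cessation groups. The share of probe sets called present ran from 67.5% to 76.2% of the array, with a median of 73.8%, and the median signal per array ran from 31.3 to 41.7. The number of arrays per group limits the precision. After filtering, 15031 genes were tested.

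The comparison of smoke with forced air at 2 weeks asked which genes respond early to smoke. The acute phase gene Saa3 (Entrez gene 20210) was at a signal of 1476 ± 289 (SD, n = 6) in smoke-exposed and 83.9 ± 21.1 (n = 6) in forced air mice, a rise (log2 change 3.91, SE 0.31, adjusted p = 7.18e-14). All 6 smoke arrays lay above all 6 forced air arrays. Untreated mice had a Saa3 signal of 80.2 ± 13.8 (n = 6). The surface protein gene Ly6i rose (log2 4.00, SE 0.32, adjusted p = 5.35e-14) and Mmp12, the macrophage elastase (Entrez gene 17381), rose 6.38-fold (log2 2.67, SE 0.24, adjusted p = 2.85e-12), each with 6 of 6 smoke arrays above every forced air array. The largest fall was that of Fabp1, a fatty acid binding protein (Entrez gene 14080), from 547.5 ± 80.6 in forced air to 155.8 ± 27.8 with smoke (log2 -1.72, SE 0.13, adjusted p = 2.2e-14, 6 of 6 arrays below).

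Genes of lipid-laden and activated macrophages were prominent among the early changes. Of 21 tested foamy or activated macrophage genes 11 rose and 1 fell at 2 weeks (12 and 1 adjusted over the list alone; camera adjusted p = 2.82e-20), among them Gpnmb (log2 2.37), the protease gene Ctsk (2.32) and the zinc transporter gene Slc39a2 (1.92). Of 25 chemokines 13 rose (15 adjusted over the list alone; camera adjusted p = 1.22e-12), including the neutrophil attractants Cxcl2 (log2 2.10), Cxcl1 (1.70) and Cxcl5, which was called present on 2 of 6 forced air arrays and whose log2 change of 2.07 is held down by the value added to each signal. Inflammatory cytokine and acute phase genes rose in 11 of 20 cases (14 adjusted over the list alone; camera adjusted p = 5.17e-14), with Orm1 (log2 2.20), Saa1 (1.81) and Csf2 (1.32) beside Saa3. Of 23 cell cycle genes 15 rose (18 adjusted over the list alone; camera adjusted p = 2.21e-16), among them Mki67 (log2 0.95), Birc5 (0.90) and Top2a (0.80). Lysosome genes rose in 12 of 27 cases (15 adjusted over the list alone; camera adjusted p = 3.95e-10) and complement genes in 7 of 14, with 1 that fell. Of 13 alveolar type 1 cell markers 6 fell (9 adjusted over the list alone; camera adjusted p = 5.78e-07), among them the water channel gene Aqp5 (log2 -0.40). Relative to untreated mice the mean of this list was 0.208 in forced air and -0.015 in smoke-exposed mice at 2 weeks. Smoke-exposed mice thus lay near untreated mice and forced air mice above them. The median Gapdh 3′/5′ ratio was 1.85 in forced air and 1.62 with smoke. Of 20 endothelial markers 5 fell (11 adjusted over the list alone; camera adjusted p = 6.26e-07) and of 18 immediate early genes 7 fell (12 adjusted over the list alone). The immediate early list lost its call with adjusted p = 0.0817 with an estimated correlation, as did the club cell markers, of which 3 of 12 fell (adjusted p = 0.349 with an estimated correlation).

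In all, 812 genes were higher and 558 lower with smoke at 2 weeks (limma, adjusted p under 0.05), and 937 were higher and 660 lower with the 3 ranges of sample title numbers as a block. With quantile normalization the split was even (698 and 686). The median 3′/5′ signal ratio of Gapdh, a measure of RNA integrity, was 1.85 in forced air and 1.62 in smoke-exposed mice, and with this ratio and that of actin as covariates 460 genes were higher and 166 lower. Without the arrays with a high ratio 574 genes were called. Leaving out forced air replicate 4 left 904 calls, and leaving out smoke replicate 2 left 905.

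After 12 weeks the question was which changes follow longer exposure. Mmp12 was at 989.7 ± 184 (n = 5) with smoke and 45.1 ± 10.7 (n = 6) with forced air, a 16.4-fold rise (log2 4.04, SE 0.25, adjusted p = 2.13e-18, 5 of 5 arrays above), beside 62.9 ± 22.5 in untreated mice. Ly6i rose 17.3-fold and Saa3 13.9-fold, the anion exchanger gene Slc26a4 9.66-fold and the chemokine gene Ccl3 8.42-fold. The lipid receptor gene Trem2 was detected in 0 of 6 forced air mice and was at least 4.83-fold higher with smoke. Cyp1b1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose 2.29-fold (log2 1.20, SE 0.11, adjusted p = 8.88e-13), while Cyp1a1 was not called (log2 -0.22, SE 0.21, adjusted p = 0.475). Fabp1 fell by 2.13 on the log2 scale and Asgr1, a subunit of the asialoglycoprotein receptor, by 1.48, both with 5 of 5 arrays below.

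Several inflammatory lists rose at 12 weeks. Of 27 lysosome genes 21 rose (21 adjusted over the list alone; camera adjusted p = 4.72e-21), of 25 chemokines 20 rose and 1 fell, of 23 cell cycle genes 21 rose (22 adjusted over the list alone) and of 21 foamy or activated macrophage genes 15 rose and 1 fell (15 and 2 adjusted over the list alone; camera adjusted p = 4.85e-22). Complement genes rose in 10 of 14 cases, including C3ar1 (log2 2.03), C1qc (1.68) and Cfb (2.10). Extracellular matrix and protease genes rose in 15 of 24 cases and fell in 3 (camera adjusted p = 2.4e-09), with the protease inhibitor genes Timp1 (log2 1.54) and Slpi (1.26) among those that rose. The mean of this list relative to untreated mice was -0.269 in forced air and 0.428 in smoke-exposed mice, so forced air lay below and smoke above untreated mice. Of 18 dendritic cell and antigen presentation genes 12 rose, among them Cd86 (at least 2.39-fold) and Cd83 (1.86-fold). Of 21 interferon response genes 11 rose, among them Cxcl10 (log2 1.76) and Oas1a (1.31), and of 18 B cell and plasma cell markers 9 rose, among them Ighm (1.71) and Jchain (1.05). The interferon list had adjusted p = 0.303 with an estimated correlation and the B cell list adjusted p = 0.473 with an estimated correlation, so both lost their calls.

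Markers of several resident lung cells fell at 12 weeks. Endothelial markers fell in 16 of 20 cases (16 adjusted over the list alone; camera adjusted p = 2.18e-07), among them Gpihbp1 (log2 -0.52). Ciliated cell markers fell in 12 of 19 cases (13 adjusted over the list alone; camera adjusted p = 2.43e-06), among them Tppp3 (-0.49) and Rsph1 (-0.49), with adjusted p = 0.104 with an estimated correlation. Smooth muscle and pericyte markers fell in 8 of 13 cases, among them Acta2 (-0.52), and had adjusted p = 0.107 with an estimated correlation. The calls of the club cell markers (7 of 12 fell), alveolar type 1 cell markers (7 of 13) and mesothelial markers (7 of 10) were lost too, with adjusted p = 0.183, adjusted p = 0.13 and adjusted p = 0.174 with an estimated correlation. Cardiac muscle markers, which a lung sample holds through its veins, fell in 6 of 14 cases (camera adjusted p = 0.00158, adjusted p = 0.473 with an estimated correlation). For several of these lists forced air lay above and smoke below untreated mice. Relative to untreated mice the means in forced air and smoke-exposed mice were 0.133 and -0.091 for type 1 and 0.113 and -0.138 for club cell markers. They were 0.12 and -0.143 for mesothelial and 0.077 and -0.19 for ciliated cell markers. For endothelial markers they were 0.036 and -0.245, and for cardiac muscle markers 0.347 and -0.242. For smooth muscle and pericyte markers both lay below untreated mice (-0.205 and -0.508). Beside these lists the Gapdh 3′/5′ ratio was 1.58 to 2.42 in forced air and 1.48 to 1.54 in smoke-exposed mice. With both 3′/5′ ratios as covariates 29 of the 57 members that fell in the 6 lists of resident cells stayed called, of 87 members tested, while the median change of the 57 went from -0.32 to -0.29 and 56 remained lower. Alveolar type 2 cell markers rose in 3 of 13 cases and the list was not called (camera adjusted p = 0.543), and Sftpc, the surfactant protein C gene, was not called (log2 -0.16, SE 0.10, adjusted p = 0.246). In all, 1880 genes were higher and 1576 lower at 12 weeks (2173 and 2092 with the ranges as a block, 1890 and 1866 with quantile normalization). With only the compared groups in the fit 1441 were higher and 950 lower. With both 3′/5′ ratios as covariates 1575 were higher and 1459 lower, and 2283 of the 3456 main calls stayed called in the same direction.

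**Figure D1:**
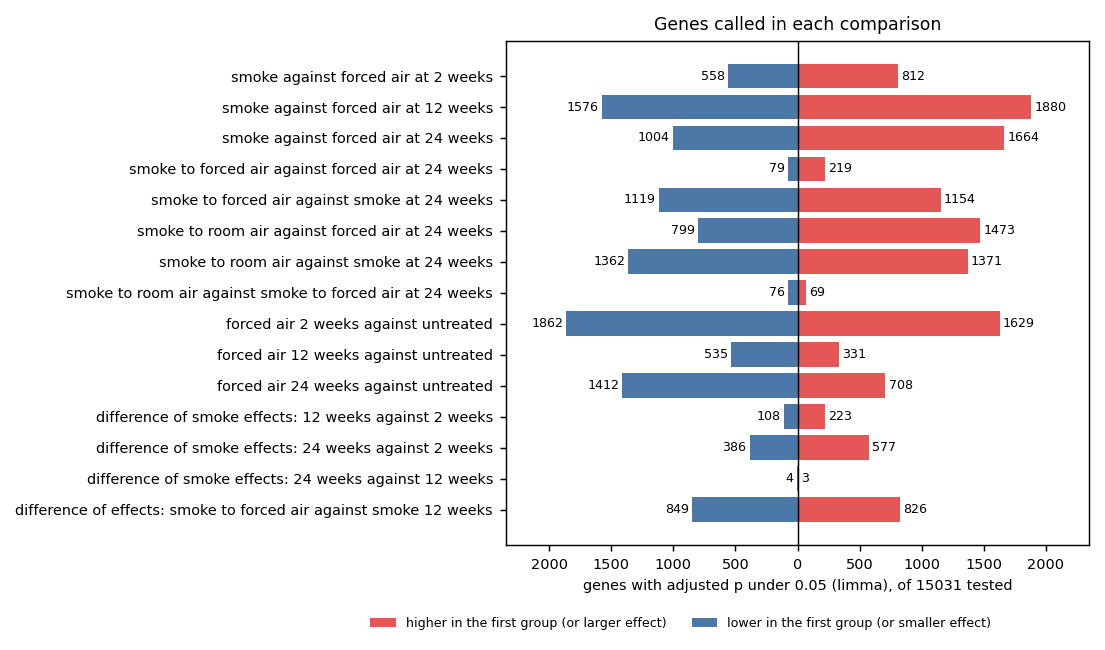
Number of genes called by limma at an adjusted p under 0.05 (horizontal axis, genes; red bars, higher in the group named earlier or a larger effect; blue bars, lower or a smaller effect) in each of 11 comparisons of groups and 4 tests of a difference between effects (vertical axis). Among the comparisons of groups the largest total was 3491 genes, for forced air at 2 weeks against untreated mice, and the smallest was for room air against forced air after smoke, with 69 genes higher and 76 lower.

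At 24 weeks the same comparison asked what continued exposure maintains. Ly6i rose 13.6-fold, Saa3 11.9-fold, Mmp12 9.82-fold (log2 3.30, SE 0.24, adjusted p = 8.22e-16) and Cxcl5 8.78-fold, all with 6 of 6 smoke arrays above every forced air array. The scavenger receptor gene Marco, a marker of alveolar macrophages, rose 6.34-fold. Slc7a11, the cystine transporter gene, rose by a log2 change of 1.39 (SE 0.13), Hmox1, the heme oxygenase gene, by 0.83 (SE 0.12) and Akr1b8 by 0.65 (SE 0.09). Ahrr, a repressor and target of the aryl hydrocarbon receptor, was at least 1.65-fold higher. Fabp1 fell by 1.46 and Asgr1 by 1.17 on the log2 scale, and the clock gene Nr1d1 by 1.02. The clock output gene Dbp fell by 0.67 (SE 0.14, adjusted p = 0.000479, 6 of 6 arrays below), while Per2 was not called (log2 -0.27, SE 0.12, adjusted p = 0.102).

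Of 27 lysosome genes 22 rose at 24 weeks (24 adjusted over the list alone; camera adjusted p = 3.14e-28), and of 21 foamy or activated macrophage genes 17 rose (18 adjusted over the list alone, where 1 also fell; camera adjusted p = 1.32e-25). Chemokines rose in 20 of 25 cases and fell in 1, cell cycle genes rose in 21 of 23, acute phase and cytokine genes in 14 of 20 and alveolar macrophage markers in 9 of 12, where 1 fell. NRF2 antioxidant and glutathione genes rose in 8 of 26 cases and fell in 3 (camera adjusted p = 0.0314; adjusted p = 0.297 with an estimated correlation). Aryl hydrocarbon receptor targets rose in 3 of 8 cases and fell in 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0476; adjusted p = 0.0769 with an estimated correlation). Of 10 mesothelial markers 6 fell, among them the transcription factor gene Wt1 (log2 -0.80, SE 0.09, adjusted p = 2.96e-09) and Lrrn4 (-0.51), and the list had adjusted p = 0.0668 with an estimated correlation. Relative to untreated mice the mean of the mesothelial list was 0.387 in forced air and 0.07 in smoke-exposed mice. It was 0.32 in smoke-to-forced-air and 0.279 in smoke-to-room-air mice, so smoke lay lowest of the 24-week groups. Endothelial markers fell in 6 of 20 cases and rose in 1 (camera adjusted p = 0.0104), with adjusted p = 0.372 with an estimated correlation. In all, 1664 genes were higher and 1004 lower at 24 weeks (1736 and 1174 with the ranges as a block). The median Gapdh 3′/5′ ratio was 1.505 with forced air and 1.51 with smoke.

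**Figure D2:**
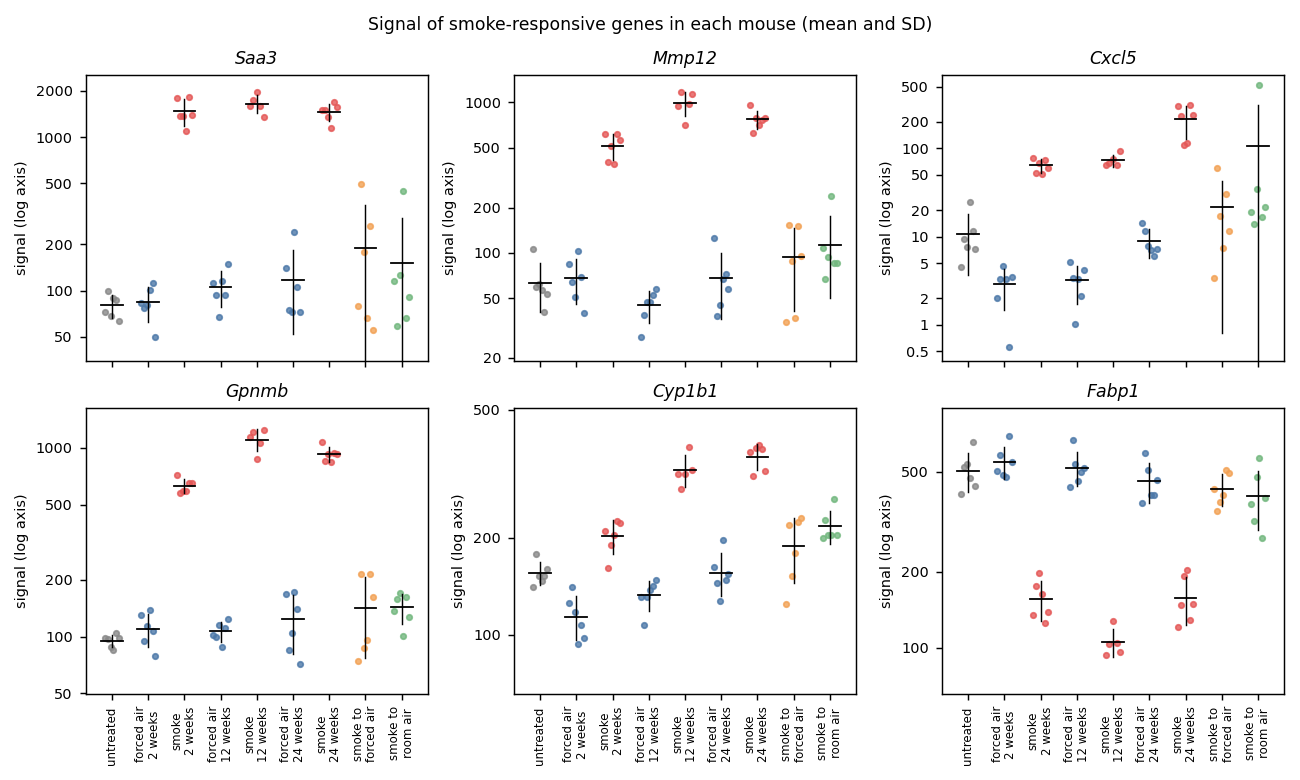
Signal (vertical axis, MAS5 signal on a log scale) of smoke-responsive genes in each of the 9 groups (horizontal axis), with a point per mouse, a horizontal line for the mean and a bar for the SD, shortened at the lower edge for Saa3 and Cxcl5 in the cessation groups. Mean Saa3 signal was 1462 after 24 weeks of smoke, 189.8 in smoke-to-forced-air and 150.6 in smoke-to-room-air mice. The highest single Saa3 signals in these 2 groups were 495.9 and 446.5, and the other 5 smoke-to-room-air mice lay from 58.6 to 126.2.

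Many genes were called at more than 1 duration. Of the genes higher at 2 weeks 627 were also higher at 12 weeks, where independent lists would share 101.6, and 519 were also higher at 24 weeks (89.9 for independent lists). Of the genes lower at 2 weeks 260 were lower at 12 weeks (58.5 for independent lists) and 90 at 24 weeks (37.3). From 12 to 24 weeks 1183 higher genes (208.1) and 524 lower genes (105.3) were shared. At all 3 durations 506 genes were higher (11.2 for independent lists) and 83 lower (3.9). No array was used at more than 1 duration. Across genes, which are not independent replicates, the changes correlated with r = 0.67 between 2 and 12 weeks, 0.50 between 2 and 24 weeks and 0.85 between 12 and 24 weeks. Without the arrays with a high 3′/5′ ratio 357 genes were shared by all durations.

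Whether the effect of smoke itself differed between durations was tested as a difference of effects. From 2 to 12 weeks it grew for the B cell chemokine gene Cxcl13 by a log2 change of 1.68 (SE 0.28, adjusted p = 0.000197), for the macrophage gene Ms4a7 by 1.47, for Ccl2 by 1.32 (SE 0.28, adjusted p = 0.00383), for Trem2 by 1.11, for the complement gene C1qc by 1.03 and for Apoe by 1.00. Of 27 lysosome genes 5 had a larger effect at 12 weeks (17 adjusted over the list alone; camera adjusted p = 1.83e-12), as had 6 of 14 complement genes, 9 of 25 chemokines and 3 of 12 monocyte and interstitial macrophage markers. In all, 223 genes were higher and 108 lower in their effect at 12 than at 2 weeks (359 and 205 with the ranges as a block). That count fell without smoke 12-week replicate 1 (205) or replicate 5 (172), without forced air 2-week replicate 2 (220) or replicate 4 (196) and without smoke 2-week replicate 2 (214), and grew without smoke 12-week replicate 3 (569). It was 505 without the arrays with a high 3′/5′ ratio and 750 with the ratios as covariates.

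From 2 to 24 weeks the effect grew for Cxcl13 (log2 1.28, SE 0.27), the galectin gene Lgals3 (0.69), Hmox1 (0.64) and the glutathione peroxidase gene Gpx2 (0.58, SE 0.11, adjusted p = 0.00225), and turned lower for Wt1 (-0.93, SE 0.13, adjusted p = 2.14e-05). Of 27 lysosome genes 14 had a larger effect at 24 weeks (17 adjusted over the list alone; camera adjusted p = 3.57e-10; adjusted p = 0.16 with an estimated correlation), and 4 of 26 NRF2 genes (7 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). Counts were 577 higher and 386 lower (485 and 361 with the ranges as a block, 837 and 1101 with all kept probe sets), and fell to 263 in all with the 3′/5′ ratios as covariates and to 568 without the high-ratio arrays. Single arrays moved the total of 963 as well. It was 522, 609, 1669 and 526 without smoke 24-week replicates 1, 2, 5 and 6, and 1614 and 597 without forced air 24-week replicates 1 and 5. It was 459 without forced air 2-week replicate 4, and 433 and 562 without smoke 2-week replicates 2 and 4.

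Between 12 and 24 weeks limma called a different effect of smoke for only 7 genes, 3 higher and 4 lower, a count that other splits of the arrays also reached, and 1414 genes had an unadjusted p under 0.05. The hexokinase gene Hk2 had a lower effect at 24 weeks (log2 -0.72, SE 0.12, adjusted p = 0.0015). Mmp12 (log2 -0.74, SE 0.35, adjusted p = 0.507) and Saa3 (-0.23, SE 0.46, adjusted p = 0.903) were not called. Of 19 ciliated cell markers none was called over all genes and 8 were higher adjusted over the list alone (camera adjusted p = 1.88e-08; adjusted p = 0.271 with an estimated correlation). The count ranged from 1 without forced air 12-week replicate 2, smoke 12-week replicate 5, forced air 24-week replicate 4, or smoke 24-week replicate 2 or 6 to 13 without forced air 12-week replicate 5. It was 2 without forced air 12-week replicate 1, 4 or 6, smoke 12-week replicate 1 or forced air 24-week replicate 3. It was 3 without forced air 24-week replicate 5 or 6 or smoke 24-week replicate 5, and 4 without smoke 12-week replicate 4, forced air 24-week replicate 2 or smoke 24-week replicate 3.

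**Figure D3:**
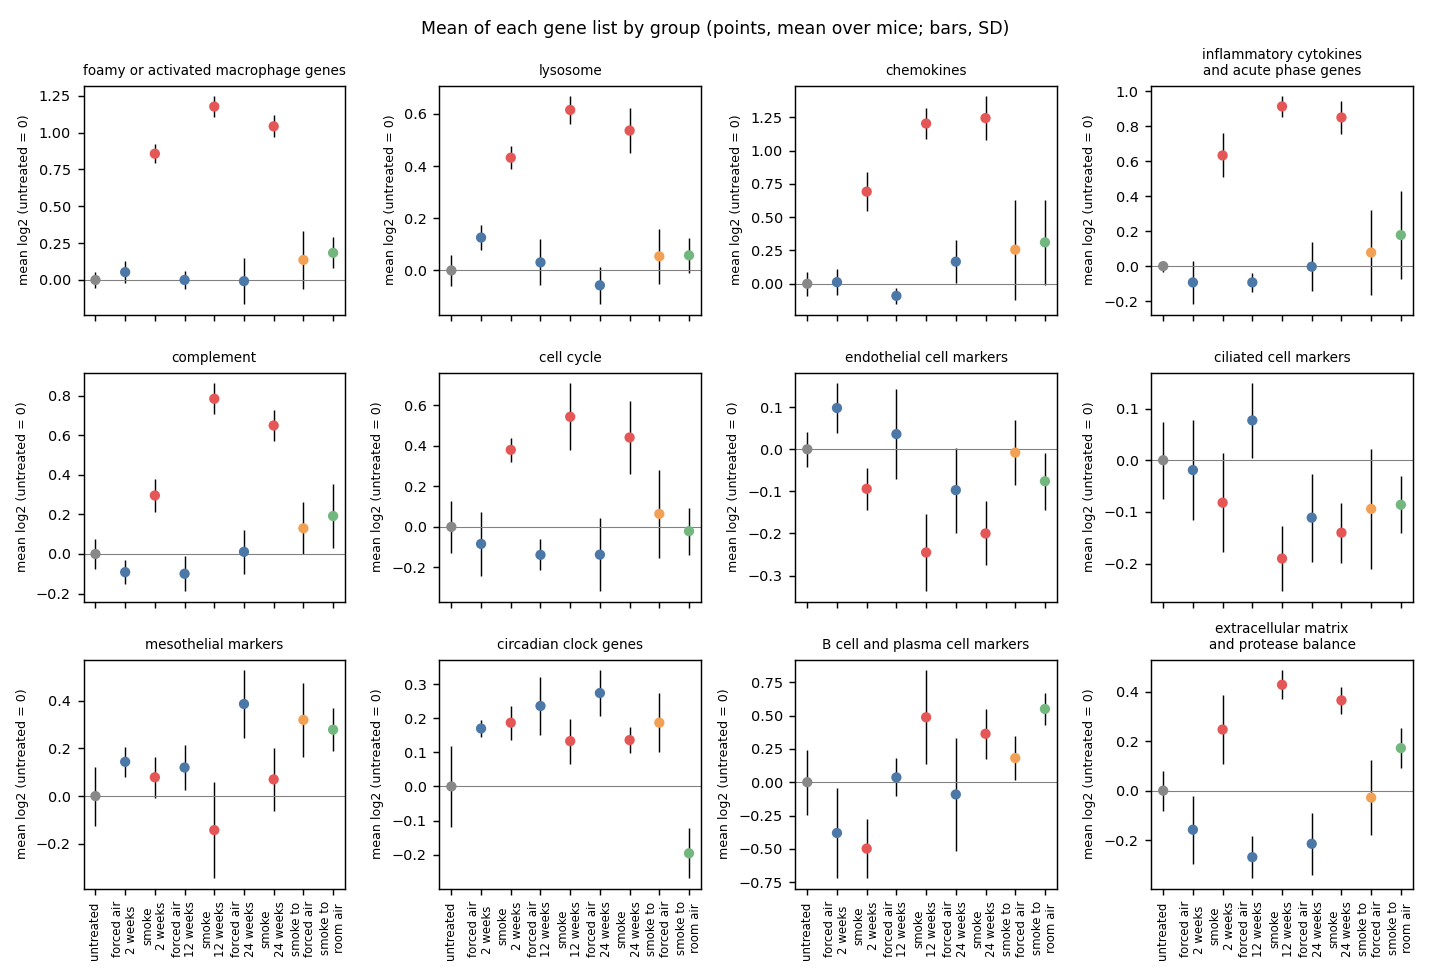
Mean log2 signal of the tested members of 12 gene lists (vertical axis, relative to the mean of untreated mice at 0) in each of the 9 groups (horizontal axis), with points for the mean over mice and bars for the SD. The smoke groups lay above their forced air groups for lysosome and foamy macrophage genes at all 3 durations, and circadian clock genes were lowest in smoke-to-room-air mice.

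Mice that stopped smoke after 12 weeks were compared with mice that went on to 24 weeks, to ask what had changed since smoke ended. In smoke-to-forced-air mice Mmp12 was at 93.2 ± 52.1 against 771.0 ± 108 with continued smoke, 7.98-fold lower (log2 -3.00, SE 0.24, adjusted p = 5.01e-14), and Saa3 was 9.28-fold lower (log2 -3.21, SE 0.31, adjusted p = 2.53e-11), each with 6 of 6 arrays below. Ly6i (log2 -3.17), Orm1 (-2.78), Cxcl5 (-2.69), Gpnmb (-2.68) and Cyp1b1 (-0.90) were lower as well, and so were Slc7a11 (-1.30) and Gclc (-0.47), which supply glutathione synthesis. Fabp1 was 2.58-fold higher (log2 1.37, SE 0.13), as were Asgr1 (log2 1.24), Nr1d1 (1.24) and Cirbp, a cold-inducible RNA binding protein gene (1.03). Of 27 lysosome genes 21 were lower (24 adjusted over the list alone; camera adjusted p = 9.52e-27), of 21 foamy macrophage genes 16 were lower and 1 higher, of 25 chemokines 19 were lower and 1 higher and of 20 acute phase and cytokine genes 13 were lower. Cell cycle genes were lower in 15 of 23 cases (18 adjusted over the list alone; camera adjusted p = 4.16e-11; adjusted p = 0.0918 with an estimated correlation). Smooth muscle and pericyte markers were higher in 10 of 13 cases (camera adjusted p = 7.14e-07) and endothelial markers in 7 of 20 (camera adjusted p = 1.74e-05; adjusted p = 0.0871 with an estimated correlation), among them Emcn (log2 0.42). In all, 1154 genes were higher and 1119 lower (1437 and 1293 with the ranges as a block).

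The comparison of smoke-to-forced-air mice with forced air at 24 weeks asked what remained 12 weeks after smoke. Several smoke-responsive genes were not called. Saa3 was at a log2 change of 0.36 (SE 0.31, adjusted p = 0.617) and Mmp12 at 0.30 (SE 0.24, adjusted p = 0.579). Cxcl5 was at 0.44 (adjusted p = 0.582) and Cyp1b1 at 0.23 (adjusted p = 0.252). The collagen gene Col5a1 was 1.29-fold higher (log2 0.37, SE 0.08, adjusted p = 0.0111, 6 of 6 arrays above). The clock gene Per2 (Entrez gene 18627) was at 515.3 ± 110 against 822.7 ± 97.8, 1.60-fold lower (log2 -0.68, SE 0.12, adjusted p = 0.00213, 6 of 6 arrays below). Of 21 interferon response genes 7 were higher (17 adjusted over the list alone; camera adjusted p = 1.63e-13) and of 20 heat shock and unfolded protein response genes 1 was lower (9 adjusted over the list alone; camera adjusted p = 1.16e-07). These lists had adjusted p = 0.193 and adjusted p = 0.12 with an estimated correlation, and none of the 16 called lists held with it. Relative to untreated mice the list means in forced air and smoke-to-forced-air mice were -0.266 (SD 0.173) and 0.211 (SD 0.308) for interferon response genes. For heat shock genes they were 0.147 (SD 0.105) and -0.089 (SD 0.129). With 24 weeks of smoke and in smoke-to-room-air mice the means were 0.137 and 0.157 for interferon response and 0.166 and -0.122 for heat shock genes. Which group carried more of each difference was not tested, and neither difference need be a remainder of smoke. In all, 219 genes were higher and 79 lower, 587 in total with the ranges as a block, and 17 were called when the fit held these groups alone. The total of 298 was 110, 73 and 467 without forced air 24-week replicates 2, 3 and 6, and lay between the first and the main total without replicate 5; it was 171, 88 and 86 without smoke-to-forced-air replicates 2, 5 and 6.

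In smoke-to-room-air mice Saa3 was lower than with continued smoke (log2 -3.46, SE 0.31, adjusted p = 2.79e-12), Mmp12 6.51-fold lower (log2 -2.70) and Gpnmb 5.99-fold lower, with 6 of 6 arrays below for each. Per2 was lower too (log2 -1.81), and Arntl, a gene of the activating complex of the clock, was higher (1.53). The immediate early gene Nr4a1 (log2 1.47), Fabp1 (1.24) and Cyp1a1 (1.04, SE 0.20, adjusted p = 7.43e-05) were higher. Of 27 lysosome genes 23 were lower (24 adjusted over the list alone; camera adjusted p = 1.93e-23), of 25 chemokines 21 were lower and 1 higher and of 23 cell cycle genes 17 were lower, the last with adjusted p = 0.0782 with an estimated correlation. Of 18 immediate early genes 10 were higher and 1 lower (camera adjusted p = 4.44e-05; adjusted p = 0.171 with an estimated correlation). In all, 1371 genes were higher and 1362 lower (1675 and 1512 with the ranges as a block).

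Against forced air at 24 weeks the smoke-to-room-air mice differed in clock, matrix and lymphocyte genes. Per2 was at 182.1 ± 28 against 822.7 ± 97.8, 4.25-fold lower (log2 -2.09, SE 0.12, adjusted p = 4.25e-19), while Arntl was 3.99-fold higher (201.1 ± 28.9 against 38.6 ± 8.3, log2 1.99, SE 0.15, adjusted p = 1.16e-14), each with 6 of 6 arrays beyond the other group. Of 17 circadian clock genes 4 were higher and 12 lower (4 and 13 adjusted over the list alone; camera adjusted p = 8.65e-11), and this was the only list whose call held with an estimated correlation (adjusted p = 9.51e-05 with an estimated correlation). The elastin gene Eln was 2.38-fold higher (log2 1.25, SE 0.11, adjusted p = 1.04e-12) and Loxl1, a crosslinking enzyme of elastic fibres, 2.32-fold higher. Extracellular matrix genes were higher in 10 of 24 cases and lower in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.0954 with an estimated correlation). The mean of this list relative to untreated mice was -0.215 in forced air and 0.172 in smoke-to-room-air mice, so forced air lay below and smoke-to-room-air mice above untreated mice. B cell markers were higher in 12 of 18 cases (camera adjusted p = 1.23e-08; adjusted p = 0.259 with an estimated correlation), among them the antigen receptor genes Cd79b (log2 1.17) and Cd79a (1.08). Glucocorticoid response genes were lower in 9 of 16 cases (adjusted p = 0.185 with an estimated correlation), among them Fkbp5 (log2 -0.88), with list means of 0.224 in forced air and -0.196 in smoke-to-room-air mice relative to untreated. Of the smoke-responsive genes Cyp1b1 (log2 0.44, SE 0.10, adjusted p = 0.00168) and Cd68 (0.41, SE 0.11, adjusted p = 0.00522) were called. Mmp12 (0.59, SE 0.24, adjusted p = 0.0857) and Saa3 (0.12, SE 0.31, adjusted p = 0.857) were not. Smoke-to-room-air replicate 4 raised both means, with signals of 239 for Mmp12 (others 67.3 to 107) and 446 for Saa3 (others 58.6 to 126). In all, 1473 genes were higher and 799 lower (1909 and 1167 with the ranges as a block). The procedure after smoke differed between these groups along with the smoke history.

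Of the 1664 genes higher with smoke at 24 weeks 6.07% were called higher than with forced air in smoke-to-forced-air mice as well, and of the 1004 lower genes 2.49% were called lower. In smoke-to-room-air mice these shares were 32.3% and 24%. Genes called as different from continued smoke in the reverse direction were 892 of the higher and 538 of the lower ones in smoke-to-forced-air mice. In smoke-to-room-air mice they were 806 and 401. A gene not called against forced air need not have returned. Over the genes called at 12 weeks, whose 12-week effects come from other arrays than the later effects, 24 weeks of smoke showed 75.8% of the 12-week effect (jackknife SE 7.2), smoke-to-forced-air mice 15.4% (SE 8.6) and smoke-to-room-air mice 23.7% (SE 8.3). Leaving out 1 array gave 10.5% to 20% and 17.8% to 28.5% for the cessation groups. With genes called at 2 weeks they showed 9.7% (SE 11.8, from 2.4% to 15.4% leaving out 1 array) and 17.7% (SE 11.8, from 9.9% to 22.4%) of the 2-week effect. These comparisons used the same forced air mice, so part of their likeness comes from shared controls. The cessation groups shared 194 higher and 73 lower genes against forced air (21.5 and 4.2 for independent lists). Simulated unchanged groups shared 0, but groups without an effect give few calls to share. That 0 therefore does not measure how many shared calls come from the shared controls. The changes of the cessation groups had a covariance of 0.023 across genes (0.00496 simulated, a difference of 0.018; 0.0178 with the controls split) and r = 0.81 (0.52 simulated, 0.53 split). Smoke at 24 weeks and smoke-to-forced-air mice had a covariance of 0.0175 (difference from simulated 0.0126; 0.0124 split) and r = 0.49 (0.52 simulated, 0.30 split), with 24.2 higher and 5.3 lower genes for independent lists. Smoke at 24 weeks and smoke-to-room-air mice had a covariance of 0.0256 (difference 0.0207; 0.0205 split) and r = 0.50 (0.52 simulated, 0.36 split), with 163.1 and 53.4 genes for independent lists. Neither of these 2 correlations lay above that of simulated unchanged groups.

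The change of the smoke effect after cessation was also tested itself, as the effect in smoke-to-forced-air mice at 24 weeks minus the effect of smoke at 12 weeks. It was lower for Mmp12 (log2 -3.74, SE 0.35, adjusted p = 1.23e-11), Saa3 (-3.44, SE 0.46, adjusted p = 1.86e-07), Ly6i (-3.53), Cxcl2 (-3.45) and Gpnmb (-3.06), and higher for Fabp1 (2.04, SE 0.19, adjusted p = 2.37e-11) and Asgr1 (1.55). Of 21 foamy macrophage genes 13 were lower (2 higher and 14 lower adjusted over the list alone; camera adjusted p = 2.67e-21), and of 20 endothelial markers 12 were higher (18 adjusted over the list alone; camera adjusted p = 1.05e-09), among them Tbx2 (log2 0.51). Ciliated cell markers were higher in 8 of 19 cases, among them Rsph1 (0.61), with adjusted p = 0.128 with an estimated correlation. Smooth muscle and pericyte markers were higher in 6 of 13 cases, among them Acta2 (0.66) and Des (0.80). In all, 826 genes were higher and 849 lower (1115 and 1047 with the ranges as a block).

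The comparison of the cessation groups with each other asked whether the air breathed after smoke mattered. Clock genes led the differences. Per2 was at 182.1 ± 28 in smoke-to-room-air and 515.3 ± 110 in smoke-to-forced-air mice (log2 -1.41, SE 0.12, adjusted p = 1.76e-12), and Dbp at 210.1 ± 60.9 and 594.7 ± 108 (log2 -1.46, SE 0.14, adjusted p = 3.2e-10), with 6 of 6 arrays below for both. Arntl was 2.51-fold higher (log2 1.33, SE 0.15, adjusted p = 7.94e-09) and its relative Npas2 2.46-fold higher. Of 17 clock genes 2 were higher and 10 lower (4 and 12 adjusted over the list alone; camera adjusted p = 2.27e-16). Of 18 cholesterol and fatty acid synthesis genes 3 were higher (10 adjusted over the list alone; camera adjusted p = 1.29e-10), among them Fdft1 (log2 0.43) and Sqle (0.37), enzymes that lead to and follow squalene. Eln was 2.08-fold higher (log2 1.06, SE 0.11, adjusted p = 3.71e-10), and Loxl1 (0.59) and Lox (0.46) were higher. Extracellular matrix genes were higher in 3 of 24 cases (adjusted p = 0.122 with an estimated correlation) and B cell markers in 1 of 18 (10 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation). Saa3 (log2 -0.24, SE 0.31, adjusted p = 0.937), Mmp12 (0.29, SE 0.24, adjusted p = 0.825) and Cyp1b1 (0.21, adjusted p = 0.487) were not called. In all, 69 genes were higher and 76 lower (136 and 123 with the ranges as a block), and 92 were called without smoke-to-forced-air replicate 4.

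**Figure D4:**
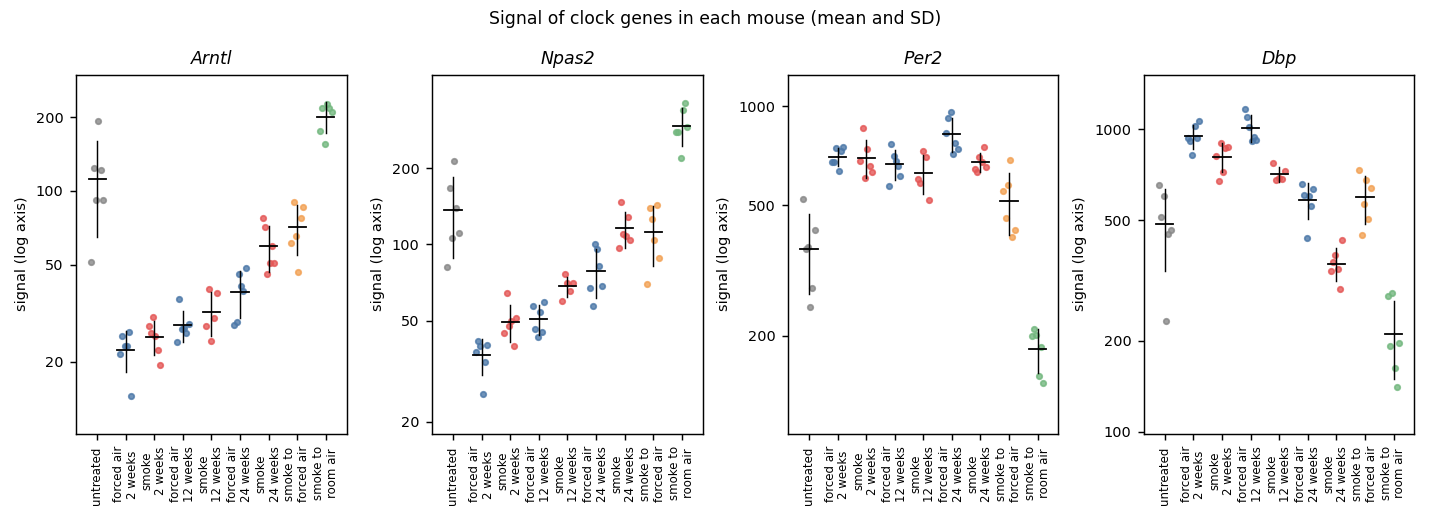
Signal (vertical axis, MAS5 signal on a log scale) of 4 clock genes in each of the 9 groups (horizontal axis), with a point per mouse, a horizontal line for the mean and a bar for the SD. Mean Per2 signal was 368.3 in untreated and 182.1 in smoke-to-room-air mice, against 702.0, 666.2 and 822.7 after 2, 12 and 24 weeks of forced air.

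Forced air groups were compared with untreated mice to measure the change in the sham groups, where time, age and the procedure go together. Arntl fell with forced air at 2 weeks (log2 -1.66, SE 0.15, adjusted p = 1.16e-11), 12 weeks (-1.46) and 24 weeks (-1.16), and Per2 rose at 2 weeks (0.94, SE 0.12, adjusted p = 8.73e-08), 12 weeks (0.86) and 24 weeks (1.16), each with 6 of 6 arrays beyond the untreated mice. Eln fell at 2 weeks, from 315.9 ± 71 in untreated mice to 129.9 ± 7.33 (log2 -1.16, SE 0.11, adjusted p = 2.4e-11), at 12 weeks (-0.89) and at 24 weeks (-0.60). Circadian clock genes rose in 11 and fell in 4 of 17 cases at 12 weeks (camera adjusted p = 1.92e-05) and rose in 9 and fell in 3 at 24 weeks (camera adjusted p = 2.5e-06), while at 2 weeks 9 rose and 3 fell with adjusted p = 0.256 with an estimated correlation. Fibroblast markers fell in 6 of 16 cases and rose in 1 at 12 weeks (camera adjusted p = 0.000107), among them the collagen genes Col1a1 (log2 -0.87) and Col3a1 (-0.76). Mesothelial markers rose in 6 of 10 cases at 24 weeks (camera adjusted p = 1.92e-06; adjusted p = 0.0572 with an estimated correlation), among them Wt1 (log2 0.76). Heat shock genes rose in 9 of 20 cases at 2 weeks (camera adjusted p = 1.35e-05; adjusted p = 0.256 with an estimated correlation), among them Hspe1 (log2 0.57). Saa3 was not called at 2 weeks (log2 0.04), 12 weeks (0.32) or 24 weeks (0.37), and neither was Mmp12 (0.10, -0.35 and 0.05).

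At 2 weeks of forced air 1629 genes were higher and 1862 lower than in untreated mice (1851 and 2244 with the ranges as a block, 1915 and 1596 with quantile normalization), at 12 weeks 331 and 535 (521 and 821) and at 24 weeks 708 and 1412 (1034 and 1795). The median Gapdh 3′/5′ ratio was 1.57 in untreated mice and 1.85, 1.75 and 1.505 after 2, 12 and 24 weeks of forced air. With the ratios as covariates 1401 genes were called at 2 weeks and 505 at 12 weeks, and without the high-ratio arrays 2034 and 476. Without forced air 12-week replicate 1 the count at 12 weeks was 574, and without untreated replicate 2 the count at 24 weeks was 1315. With only the compared groups in the fit 276 genes were called at 12 weeks and 1109 at 24 weeks. With the number within the group in the sample title as a block 177 were higher and 393 lower at 12 weeks.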

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

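The tests of dilution and of RNA quality as the whole cause for resident cell markers, and of correlation between cardiac markers, were chosen after the results were seen, while those of single-member RNA quality, scaling and the spread between mice were written before. In 17 of 216 groups of values, over 24 measures, a single array lay apart from the others of its group by Dixon's criterion, which chance alone meets in about 1 in 20 groups. Untreated replicate 2 had the lowest median signal of its group (31.35) and the highest 3′/5′ ratios of Gapdh (1.972) and actin (2.877), and smoke 24-week replicate 2 had an actin ratio of 2.092, each far from the other arrays of its group. The highest signal on the array was 10456 for forced air 2-week replicate 6, 10416 for forced air 12-week replicate 1 and 9788 for smoke 24-week replicate 2, far above the other arrays of each group. The same 3 arrays had outlying signals of Sftpc, at 4918, 4504 and 4235. Smoke-to-room-air replicate 4 stood above its group for Mmp12 (238.7), Saa3 (446.5) and Cxcl5 (529.2), and replicate 5 of that group for Gclc (736.6). Single arrays lay below their groups for Ccl2 in forced air 2-week replicate 3 (19.78), for Cd79a in smoke 2-week replicate 2 (34.67) and for Dbp in untreated replicate 4 (233).

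The effect of smoke differed between durations, or after cessation, by the test of the difference itself. From 2 to 12 weeks it differed for 331 genes, from 2 to 24 weeks for 963 and from 12 to 24 weeks for 7. Between 12 weeks of smoke and cessation to forced air it differed for 1675. Splits of the arrays did not exclude chance for these differences of effects. Among the genes of the fixed panel, the effect was larger at 12 than at 2 weeks for Ccl2 (log2 1.32) and Mmp12 (1.37), the latter not called without forced air 2-week replicate 4 (1.26), without smoke 12-week replicate 5 (1.31) or without the high-ratio arrays. It was larger at 24 than at 2 weeks for Gpx2 (0.58) and for Cd68 (0.51). The Cd68 call was lost without forced air 2-week replicate 1 (0.48), 2 (0.47) or 4 (0.48), smoke 2-week replicate 2 (0.49) or 4 (0.50), forced air 24-week replicate 2 (0.45), 3 (0.47) or 5 (0.49), or smoke 24-week replicate 2 (0.45) or 6 (0.47), and also without the high-ratio arrays (0.55) and with the ratios (0.46) or the title number (0.51) as covariates. After cessation the effect was higher than at 12 weeks for Gpx2 (0.53) and Pecam1 (0.45), and lower for Gclc (-0.57), Per2 (-0.58; not called with the ratios as covariates, at -0.48), Cyp1b1 (-0.97), Cd68 (-1.16), Cxcl5 (-1.77), Ccl2 (-2.32), Saa3 (-3.44) and Mmp12 (-3.74). Probe sets without a single gene name, which the gene comparisons left out, were called too, in 259 of 7205 cases for smoke at 2 weeks, 901 at 12 weeks and 791 at 24 weeks, among 35615 probe sets tested together.

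Markers of endothelial, ciliated, smooth muscle, club, type 1 and mesothelial cells fell after 12 weeks of smoke, in 57 of 87 cases. Dilution of all resident cells alike by recruited cells would lower all lists equally only if recruited cells lacked these markers, which was not tested. The value added to each signal also draws changes of dim genes towards 0. Over all 8 lists of resident cells, type 2 and fibroblast markers included, the changes of the list medians ran from -0.30 to -0.02. They were unequal once the shift shared by the lists of a mouse was removed (exact permutation p = 0.00433, one-sided, 462 splits). This argues against an equal change of all lists but cannot exclude dilution. The choice of scaling mattered little, since 94.7% of the members that fell stayed called with quantile normalization. That method also sets all arrays to a common distribution, and it raised the lower calls at 12 weeks from 1576 to 1866. A shift that both ways of scaling share could therefore not be excluded. With the 3′/5′ ratios as covariates only 50.9% stayed called. The median change of these members went from -0.32 to -0.29 and the median SE from 0.088 to 0.091, and 56 stayed lower. The part of RNA quality in single members was therefore not settled. The mean of all members remained at -0.21 (SE 0.03) with the covariates against -0.27 (SE 0.03) without. However, the Gapdh ratios of the 12-week groups did not overlap (1.58 to 2.42 with forced air, 1.48 to 1.54 with smoke). The adjustment thus rested on the spread within groups, and the lists averaged were those seen to fall. RNA quality as the whole cause of the lower list means was therefore not excluded. A loss or shift of some resident cells stays open as a hypothesis.

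Cardiac muscle markers were lower after 12 weeks of smoke, with a list mean of -0.59 on the log2 scale over 14 markers. Their deviations from the group means rose and fell together, with a median correlation between markers of 0.84, so a possible explanation is more or less heart muscle of veins or nearby tissue in each sample. The smoke and forced air groups differed beyond the spread between mice (exact permutation p = 0.0152, two-sided, where the smallest possible was 0.00216). Relative to untreated mice, which spanned from -0.47 to 0.28, the mean was 0.347 with forced air and -0.242 with smoke, so the smoke mean lay inside that span and the forced air mean above it, and which group moved, and whether through the dissection or in the mice, was left open.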

How the results depend on the processing

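The title ranges as a block, the arrays left out for brightness or for a high 3′/5′ ratio, the ratios as covariates and the replicate block were alternatives chosen after seeing the data. Of 986 named gene results, the call and direction were the same in 958 with quantile normalization, 972 with a pseudocount of 1, 955 without the detection filter, 957 with all kept probe sets, 949 with the title number as a covariate, 972 with the ranges as a block, 947 without the bright arrays, 876 with only the compared groups in the fit, 881 without the high-ratio arrays, 888 with the ratios as covariates and 493 with a minimum absolute log2 change of 1. Most of the rest lost their call. When 1 array was left out, 184 of the 986 changed their call in at least 1 case. The change of Cbr2 for smoke at 12 weeks was lost with the ratios as covariates (0, against -0.28), and no called result took the opposite direction. Its call was also lost with quantile normalization (-0.13). Low signals limit precision, because the value added to each signal draws their changes towards 0.

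With all kept probe sets, more features, calls were 2077 (smoke at 2 weeks), 6118 (12 weeks), 4811 (24 weeks), 3654 (smoke-to-forced-air against smoke), 4380 (smoke-to-room-air against forced air), 4945 (smoke-to-room-air against smoke), 225 (between the cessation groups), 6198, 1433 and 3964 (forced air at 2, 12 and 24 weeks against untreated), 1938 (24 against 2 weeks of smoke), 3 (24 against 12 weeks), 2714 (cessation against 12 weeks of smoke) and 922 (called at all 3 durations). With a minimum absolute log2 change of 1, a stricter call, they were 68 (2 lower), 209 (6) and 143 (6) for smoke at 2, 12 and 24 weeks, 1 and 92 for smoke-to-forced-air against forced air and smoke, 46 for smoke-to-room-air against forced air, 18 higher and 87 lower (1.1e+02 in all) for it against smoke, 13 between the cessation groups, 10, 9 and 15 for forced air against untreated, 35, 14 and 2 for the differences between durations, 132 for cessation and 61 at all durations.

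With only the compared groups in the fit, hence fewer arrays for the spread, calls were 17 for smoke-to-forced-air against forced air, 276 and 1109 for forced air at 12 and 24 weeks against untreated, and 2 for 24 against 12 weeks. For the settings that follow the cause was not tested. Quantile normalization gave 505 for 12 against 2 weeks and 1498 for 24 against 2 weeks. The title number as a covariate gave 533 for 24 against 2 weeks and 3 for 24 against 12 weeks. For 24 against 12 weeks a pseudocount of 1 gave 4 and no detection filter gave 2. The ranges as a block gave 587 for smoke-to-forced-air against forced air, 259 between the cessation groups, 1342 for forced air at 12 weeks against untreated and 564 for 12 against 2 weeks. Without the 3 bright arrays there were 575 for 12 against 2 weeks and 1 for 24 against 12 weeks. Without the high-ratio arrays there were 574 (smoke at 2 weeks), 503 (smoke-to-forced-air against forced air), 2034 and 476 (forced air at 2 and 12 weeks against untreated), 505, 568 and 2 (differences between durations) and 357 (all durations). With the ratios as covariates there were 626 (smoke at 2 weeks), 1401 and 505 (forced air at 2 and 12 weeks), and 750, 263 and 2 (differences between durations). The lists called fell from 231 to 70 with an estimated correlation. Smoke at 24 weeks showed 97% (SE 15.3) of the 2-week effect with genes picked at 2 weeks, against 75.8%.

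The share of calls that were higher moved by over 10 points in some of these settings. With the minimum change smoke calls were 97.1%, 97.1% and 95.8% higher at 2, 12 and 24 weeks, against 59.3%, 54.4% and 62.4%, and those of smoke-to-forced-air against smoke, smoke-to-room-air against smoke and cessation against 12 weeks were 6.5%, 17.1% and 6.8%, against 50.8%, 50.2% and 49.3%. It was 53.3% against 33.4% for forced air at 24 weeks against untreated, 100% against 73.5% for the 1 call of smoke-to-forced-air against forced air, and 100%, 92.9% and 0% against 67.4%, 59.9% and 42.9% for the differences between durations. For smoke at 2 weeks it was 59.3% in the main comparison and 73.5% with the ratios as covariates, and for forced air at 2 weeks against untreated 46.7% and 59.3% without the high-ratio arrays. For 24 against 2 weeks of smoke it was 59.9%, 43.2% with all kept probe sets and 75.7% without the high-ratio arrays. All kept probe sets also gave 49.7% against 33.4% for forced air at 24 weeks against untreated, 60.7% against 73.5% for smoke-to-forced-air and 54.7% against 64.8% for smoke-to-room-air against forced air. Only the compared groups in the fit gave 58.8% for smoke-to-forced-air against forced air, and 62.9% against 47.6% between the cessation groups. Quantile normalization moved it by at most 9.7 points, yet it evened the split for smoke at 2 weeks (50.4% against 59.3%) and 12 weeks (50.3% against 54.4%), and it turned the majority for forced air at 2 weeks against untreated (1915 higher and 1596 lower), for smoke-to-forced-air against smoke (1222 and 1297), for smoke-to-room-air against smoke (1523 and 1524) and for cessation against 12 weeks of smoke (1091 and 898), and between the cessation groups (50.7% higher).

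Leaving out 1 array at a time gave 904 to 1429 calls for smoke at 2 weeks, 2722 to 3476 at 12 weeks and 2134 to 2936 at 24 weeks. It gave 73 to 467 for smoke-to-forced-air against forced air and 1813 to 2234 against smoke, 1741 to 2311 for smoke-to-room-air against forced air and 2332 to 2688 against smoke, and 92 to 150 between the cessation groups. For forced air against untreated it gave 2494 to 3893 at 2 weeks, 574 to 951 at 12 weeks and 1315 to 2369 at 24 weeks. The differences between durations ranged from 172 to 569 (12 against 2 weeks), 433 to 1669 (24 against 2) and 1 to 13 (24 against 12), cessation against 12 weeks of smoke from 1426 to 1813, and calls at all durations from 515 to 611.

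The titles also hold a number within each group of unstated meaning, and compared groups shared 1 to 4 of them. Over 26 same-numbered matches the deviations from group means correlated from -0.481 to 0.496, over 0.1 in 9, and in 3 each array correlated best with its own number, so the arrays were taken to share only a number. In forced air at 12 weeks against untreated mice all 3 matches lay above 0.1 (0.103 to 0.242). With this number as a replicate block, with fewer degrees of freedom, calls were 654 and 1241 for smoke-to-forced-air against forced air and smoke, 39 between the cessation groups, 1646 and 570 for forced air at 2 and 12 weeks against untreated and 2 for 24 against 12 weeks of smoke (0% higher, against 42.9%), and the other 10 counts moved by less than 1.5 times. Of the 986 named gene results 849 kept their call and direction.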

Other observations

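The tests of title ranges, of single mice and of a shared clock shift below were chosen after the results were seen, and the test of the remaining genes was written before. Several gene lists had not been described. Cholesterol efflux and lipid handling genes rose in 6 of 16 cases and fell in 1 at 2 weeks of smoke (camera adjusted p = 0.00702), rose in 8 and fell in 2 at 12 weeks (7.2e-06) and rose in 8 at 24 weeks (3.4e-06), and in smoke-to-forced-air mice 7 were lower than with continued smoke (6.38e-05). All of these list calls held with an estimated correlation. Examples at 12 weeks were the scavenger receptor genes Msr1 (log2 2.67, SE 0.16, 5 of 5 arrays above) and Olr1 (1.58, SE 0.14, 5 of 5 arrays above). Of 17 T and NK cell markers 5 rose at 12 weeks, among them Ctla4 (log2 1.34) and the costimulation gene Icos (1.05). Adjusted over the list alone 7 rose (camera adjusted p = 0.0216, and adjusted p = 0.484 with an estimated correlation). Of 14 goblet cell and mucus genes 2 rose at 2 weeks (camera adjusted p = 0.0164; adjusted p = 0.354 with an estimated correlation), Slc26a4 and the immunoglobulin receptor gene Pigr (1.17). Relative to untreated mice the mean of the goblet list was -0.388 in forced air and -0.004 in smoke-exposed mice. Smoke-exposed mice thus lay near untreated mice and forced air mice below them.

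Neutrophil markers were not called with smoke at 2 weeks (3 of 14 rose and 1 fell, camera adjusted p = 0.684), 12 weeks (0.0509) or 24 weeks (0.226), beside the rise of neutrophil-attracting chemokines. S100a8 was not called at any duration, with log2 changes of -0.21, -0.06 and 0.27. Pentose phosphate and NADPH supply genes were called as a list in no comparison, with 1 of 8 rising at 12 weeks (camera adjusted p = 0.223). The mucin gene Muc5b was not called at 2 (log2 0.05), 12 (-0.15) or 24 weeks (0.01) of smoke. Heat shock and unfolded protein response genes were lower in 8 of 20 cases in smoke-to-forced-air than in smoke-exposed mice (camera adjusted p = 7.39e-06; adjusted p = 0.0559 with an estimated correlation), among them the chaperone gene Sdf2l1 (log2 -0.93).

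Room and forced air after smoke differed in 69 higher and 76 lower genes, 12 of 17 clock genes among them. Unequal title number ranges between the groups were argued against, since all 12 clock genes stayed called in the same direction with the ranges as a block. Over these genes a median of 6 of 6 mice lay beyond every mouse of the other group, so a few mice did not carry these calls. The genes were picked as called on the same arrays, which favours such a separation, so it is no independent test. A candidate explanation is a clock shift shared by mice kept out of the exposure chamber, and in line with it all 12 had the same direction in untreated mice against forced air at 12 weeks. Of the 133 other genes 91% had the same direction in that comparison too (exact permutation p = 0.013, one-sided, smallest possible 0.00108, with a median of 50% over 924 splits), which may reflect housing, handling or the hour of sampling, and these could not be separated. The hypothesis was found in these data, no mice breathed room air alone for 24 weeks, and only 64.7% of the genes that differed between smoke-to-room-air mice and forced air at 24 weeks shared the direction. Groups held in the chamber also differed among themselves at 24 weeks. Relative to untreated mice their clock list means were 0.274 (SD 0.067) with forced air, 0.136 (SD 0.037) with smoke and 0.187 (SD 0.087) in smoke-to-forced-air mice. The mean was -0.196 (SD 0.073) in smoke-to-room-air mice. Time out of the chamber does not account for the differences among the chamber groups.

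Smoke-to-room-air replicate 4 was examined after its values were seen. Its chemokine list mean was 0.77 on the log2 scale relative to forced air at 24 weeks, against -0.14 to 0.14 in the other mice of its group and 0.87 to 1.34 with 24 weeks of smoke. Its acute phase and cytokine list mean was 0.68 (others 0.02 to 0.14). Its Ly6i signal was 609 (others 40.1 to 57.7) and its Slc26a4 signal 476 (others 62.3 to 108). Its foamy macrophage list mean was 0.38, between the others (0.07 to 0.25) and smoke (0.95 to 1.15), and its Ctsk signal of 153 lay within the others (103 to 169) and below smoke (586 to 727). Its clock list mean was -0.60 (others -0.49 to -0.40).

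Other splits of the same arrays into groups of the same sizes were drawn, 100 per comparison with the real one included, and for differences between effects weeks were exchanged within smoke and within air. With 100 splits the smallest share that can be reached is 1 in 100, which over 15 comparisons cannot exclude chance. In several comparisons only 1 split called as many genes, the real one, which argues against chance for each by itself. This held for smoke at 2 weeks (1370 calls, highest other 674), 12 weeks (3456, 978) and 24 weeks (2668, 1535). It held for smoke-to-forced-air against smoke (2273, 1008) and for smoke-to-room-air against forced air (2272, 1153) and smoke (2733, 1323). Smoke-to-room-air against smoke-to-forced-air had 69 higher and 76 lower genes, with the highest other split at 30. Forced air against untreated held too, at 2 weeks (3491, 2993), 12 weeks (866, 576) and 24 weeks (2120, 1604). For 12 against 2 weeks of smoke (331, 255) and cessation against 12 weeks (1675, 1210) no other split reached the real count. Exchanging weeks tests whether weeks differ at all, so the splits cannot exclude chance for a difference of effects. For smoke-to-forced-air against forced air 3 of the 100 splits called at least the real 298, the highest other 1420, and for 24 against 2 weeks 4 called at least 963, the highest other 2933. Both counts lay under the limit of 5 of 100 splits set for each comparison by itself. Over 15 comparisons such counts can arise by chance, so chance was not excluded there. For 24 against 12 weeks 10 of the 100 splits called at least the real 7, the highest other 2239, and chance was not excluded. Splits that call several times the real count, as in the last 3 cases, point to a structure of the samples. The highest other split for smoke-to-forced-air against forced air parted the arrays of the middle title range by 5 and so followed the ranges, and with the ranges as a block the real comparison called 587 genes. The highest split for forced air at 24 weeks against untreated followed the ranges in the same way, and the real comparison called 1034 higher and 1795 lower genes with the block. That of 24 against 12 weeks did too, with a difference of 6 between the smoke and forced air groups at 24 weeks. The real test called 10 genes with the block. For 24 against 2 weeks the highest split parted the middle range by 3 and the real one by 2, counted over the 24-week groups alone. The 2-week groups were not counted, so whether the ranges account for that structure cannot be told. The real test called 846 genes with the block, of which 713 were also called without it.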
